A study of Danio rerio with 14 samples.

How the data were processed

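RNA was sequenced from whole zebrafish embryos, mttp mutants and siblings, at 24 hpf (4 libraries each) and 48 hpf (3 libraries each). Per the labels, 1 µg of total RNA extracted with TRIzol went into libraries made with the NEBNext Ultra RNA kit, a kit that does not mark the strand. Nothing in the labels says that the replicates are separate clutches, so the p-values measure the spread between these samples. The batch label of each library equals its stage, so stage and batch cannot be told apart; both are shared by the mutants and siblings of a stage.

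The deposited values are raw read counts per gene, whole numbers that the authors made without a normalization, from 1 table with 1 column per library. The authors' processing named FastQC 0.12.1, Trim Galore 0.6.10, STAR 2.7.10b, featureCounts 2.0.6 and the genome build GRCz11. The gene annotation, the strand setting and the treatment of reads that map to several places are not given in the sources used here. Reads shared between similar genes (apobb.1 and apobb.2, the crygm2d family, the hatching enzymes, the hsp70 genes) can therefore have been counted for either member or for none. The table held 36109 genes, of which 4130 had no count in any library. Library totals ranged from 29422983 to 46534187 counts.

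Genes were tested with edgeR 4.0.16 (limma 3.58.1, R 4.3.3): quasi-likelihood fits (glmQLFit, glmQLFTest) on raw counts with TMM factors, after filterByExpr with a minimum count of 10. The filter kept 24424 genes holding 100.0% of the counts. All 14 libraries were fitted together as 4 groups, with 10 residual degrees of freedom and a common dispersion of 0.0580. The contrasts were mutants against siblings at 24 and at 48 hpf, the difference between these effects (48 minus 24 hpf), and 48 against 24 hpf in siblings. A gene was called at a Benjamini-Hochberg adjusted p under 0.05. CPM are scaled with TMM factors, and the SE of a log2 fold change was taken from the fit. The shared calls of both stages were compared with the product of their shares by one-sided Fisher's exact tests.

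In total 37 gene lists were tested with camera (two-sided) on log2 CPM with a prior count of 2, a preset inter-gene correlation of 0.01 and adjustment over the lists of a contrast. Lists needed at least 5 tested members, 25 of them share members with another list, and mttp is in none. Of the listed names, 21 were matched through a RefSeq synonym and 30 were not found. Camera asks whether a list moved relative to the other genes. With the correlation estimated from the data, 3 of the 15 calls at 24 hpf held (ER stress, fasting and Foxo targets, oxidative phosphorylation), 5 of 24 at 48 hpf (Atf4 targets, cholesterol synthesis, heat shock, hatching gland, lipid droplets), 3 of 21 for the difference between stages and 2 of 11 in siblings. The fry test, an alternative, asks whether a list moves on balance without comparing it with other genes. Members called were counted over all genes tested and adjusted over the list alone.

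The contrasts, lists, thresholds, alternatives and the rule for naming genes were fixed before the data were examined. The rule named mttp, a fixed set of genes of the lipoprotein axis, the 12 genes with the greatest rise and the 12 with the greatest fall per mutant contrast, and 6 and 6 for the other contrasts. These needed an adjusted p under 0.05, an average log2 CPM of at least 1, a gene name other than a clone identifier and, within a stage, all mutant libraries on one side of all sibling libraries. It also named up to 4 called members of each list, those with the smallest p. Exceptions are named where they appear. A fold against a group with 0 counts is given as a lower bound from a floor of 3 counts over the group; intervals and floors cover counting error only.

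The alternatives were DESeq2 1.42.0, limma-voom, RLE size factors, library size only, no low-count filter, a CPM of at least 1 in 3 libraries, at least a 2-fold change, leaving out each library in turn, the replicate number as a block, the libraries of the stage only, and both of the latter together. For lists they were the estimated correlation, fry and leaving out members shared with another list. An alternative chosen after the data were seen left out both libraries of low mitochondrial share, sibling replicate 2 at 24 hpf and sibling replicate 3 at 48 hpf. Names and the order of neighbouring genes came from a RefSeq table of the assembly GRCz12tu, used for names, gene spans and neighbours only.

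The fit was tested on simulated counts, with 200 genes changed. At 24 hpf it recovered 32.8%, 62.7% and 90.9% of genes changed 1.5-fold, 2-fold and 4-fold, and 8 of 132 called genes were unchanged ones. At 48 hpf it recovered 20.9%, 50.7% and 86.4% (5 of 110 unchanged), and for the difference between stages 2.99%, 37.3% and 72.7% (3 of 78 unchanged).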

Results

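Whole zebrafish embryos mutant for mttp were compared with their siblings at 24 and 48 hours post fertilization (hpf) by RNA sequencing. The gene mttp encodes the microsomal triglyceride transfer protein, which loads lipid onto apolipoprotein B so that yolk lipid can leave the yolk syncytial layer, the lipid-exporting layer around the yolk, as lipoprotein particles. The comparison addresses which genes respond when lipid export from the yolk is impaired, and whether genes of the Hnf4 and lipoprotein axis are among them. Changes are log2 fold changes of mutants against siblings ± SE, with adjusted p-values from edgeR's quasi-likelihood test (Benjamini-Hochberg), unless another test is named. The 24 hpf groups held 4 libraries each and the 48 hpf groups 3 each.

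RNA of mttp was lower in the mutants at both stages, in every mutant library against every sibling library of its stage. At 24 hpf mttp measured 9.68 ± 1.51 CPM (counts scaled to library size with TMM factors; mean ± SD, n = 4) in mutants, from 7.90 to 11.3, and 71.2 ± 5.77 in siblings, from 67.3 to 79.6. Its log2 fold change was -2.88 ± 0.21, adjusted p = 1.57e-07. At 48 hpf it measured 8.40 ± 2.703 CPM (n = 3) in mutants, from 6.23 to 11.4, and 29.4 ± 9.62 in siblings, from 19.3 to 38.5. The log2 fold change there was -1.81 ± 0.23, adjusted p = 8.12e-05.

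**Figure D1:**
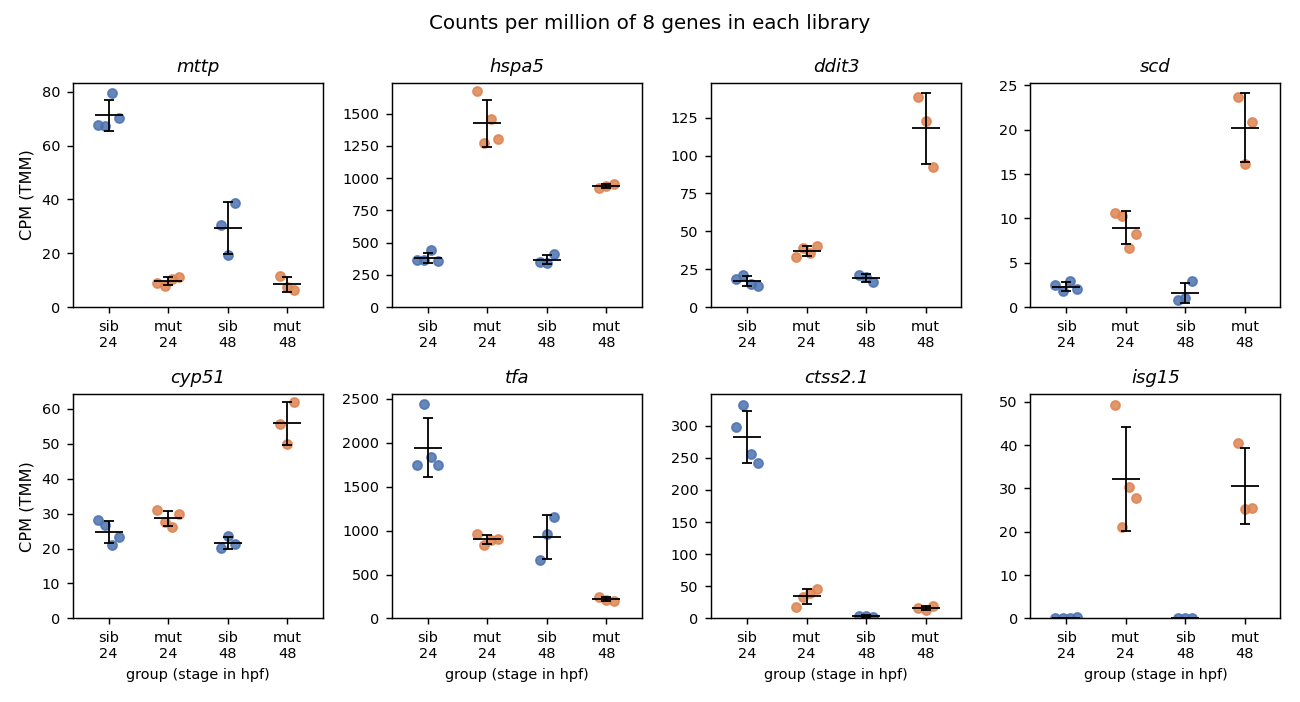
CPM of mttp, hspa5, ddit3, scd, cyp51, tfa, ctss2.1 and isg15 in each library (y axis, linear from 0) for siblings and mutants at 24 and 48 hpf (x axis); points are libraries and bars are the mean ± SD. Mutant means of isg15 were 32.2 and 30.5 CPM at 24 and 48 hpf, against 0.123 and 0.0623 in siblings, while the ctss2.1 mean was lower in mutants at 24 hpf and higher in them at 48 hpf.

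At 24 hpf the mutants had more RNA of genes that fold and clear proteins in the endoplasmic reticulum (ER) and less of nuclear genes for the mitochondrial respiratory chain, list calls that held with an estimated correlation between genes. With the preset correlation only, lists of fatty acid synthesis and lipid droplet genes were called higher, and lists of plasma protein, apolipoprotein and ribosome assembly genes lower. Of 24424 genes tested, 366 were called higher and 568 lower, and 154 and 132 of these changed at least 2-fold. Thus 39.2% of the called genes were higher. Scaling by library size only, which moved the median of all genes by 0.10 on the log2 scale, gave 550 higher and 313 lower genes, or 63.7% higher.

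Among the genes with the greatest rise that met the naming rule, isg15, a ubiquitin-like modifier made in response to interferon, went from 0.123 ± 0.0862 to 32.2 ± 12.05 CPM (7.99 ± 0.41, adjusted p = 5.37e-09). The gene derl3, which helps to pull misfolded proteins out of the ER, rose by 4.68 ± 0.14, adjusted p = 3.81e-12, and dnajb9b, a co-chaperone of the ER, by 3.58 ± 0.26, adjusted p = 2.26e-07. The gene tmem86b, whose product cleaves plasmalogen lipids, rose by 5.60 ± 0.55, pmt, which methylates phosphoethanolamine, by 4.00 ± 0.24, and fep15, a fish selenoprotein of the ER, by 3.40 ± 0.33. The genes ush1c, a scaffold of hair cells and gut, clstn3, a calsyntenin of cell membranes, trpc2a, a cation channel, abcc12, a membrane transporter, and lgals2b, a sugar-binding galectin, rose by between 3.16 and 4.14. The gene agt, the precursor of angiotensin, rose by 3.22 ± 0.65, adjusted p = 0.00801, but limma-voom did not call it, and its adjusted p ranged from 1.96e-06 to 0.417 over the alternatives.

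Apart from mttp itself, by the same rule the greatest falls were those of ctss2.1, a lysosomal cathepsin (-3.04 ± 0.24, adjusted p = 3.96e-07), and sardh, which breaks down sarcosine in mitochondria (-2.83 ± 0.21, adjusted p = 2.78e-07). The gene slc10a1, a bile acid transporter, fell by 2.60, dao.1, which oxidizes D-amino acids, by 2.60, and acot17, which splits acyl-CoA, by 2.54. The genes rdh5, a retinol dehydrogenase, cyp1c1, a cytochrome P450, slc24a3, a cation exchanger, cfhl1, a relative of complement factor H, vtna, a vitronectin, and akr1a1a, an aldehyde reductase, changed by between -2.51 and -2.18.

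Of the genes fixed for naming, creb3l3a, a transcription factor of lipid metabolism, rose by 0.88 ± 0.15, adjusted p = 0.00144, and igfbp1a, a fasting-induced binder of insulin-like growth factors, by 1.28 ± 0.16, adjusted p = 1.05e-04. An apolipoprotein B gene, apoba, fell by 0.76 (adjusted p = 0.00300). The cholesterol synthesis gene hmgcs1 rose by 0.56 ± 0.13, adjusted p = 0.0181. Its call was lost without sibling replicate 3 (0.0688) or mutant replicate 1 (0.0658) or 3 (0.0533; range from 7.11e-04). The gene hnf4a, the nuclear receptor of the axis, was not called (-0.74 ± 0.25, adjusted p = 0.123; range 0.00863 to 0.344). A replicate block or leaving out mutant replicate 2 (0.0339) called it lower. Neither apoa1b (-0.39 ± 0.15, adjusted p = 0.176; range 0.00226 to 0.396) nor pla2g12b, a partner of lipoprotein assembly (-0.49 ± 0.15, adjusted p = 0.0926; range 4.24e-04 to 0.252) was called. The block and the libraries of the stage alone (0.0291 and 0.00303) called both lower, and DESeq2 the latter (0.0242). The genes apobb.1 (-0.31; range 0.00377 to 0.515), igf1 (0.66), igf2b (-0.22), ldlra (0.79) and flt1 (0.47) were not called, with adjusted p-values from 0.210 to 0.541. The block called apobb.1 lower.

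The list of ER stress genes, whose products fold proteins in the ER, had the lowest camera adjusted p, 1.86e-36, and 0.0163 with an estimated correlation. In this list 23 rose and 7 of 30 tested members were not called (adjusted over the list alone, 25 rose and 1 fell). Its chaperones hspa5 (1.90 ± 0.10), hyou1 (2.08 ± 0.11), dnajc3a (2.14 ± 0.12) and hsp90b1 (2.73 ± 0.15) each had an adjusted p of at most 7.45e-09. For targets of Atf4, which answers amino acid and ER stress, 8 rose, 2 fell and 28 of 38 tested members were not called (adjusted over the list alone, 13 rose and 2 fell) (adjusted p = 0.00266, and adjusted p = 0.184 with an estimated correlation). In that list atf5a (1.09 ± 0.12), sesn2 (1.09 ± 0.14) and ddit3 (1.1004 ± 0.14), regulators of stressed cells, rose, whereas the amino acid transporter subunit slc3a2a fell (-1.2997 ± 0.17). Fasting and Foxo targets were also called higher, and this held with an estimated correlation (adjusted p = 0.00450 and 0.0440): 5 rose, 2 fell and 31 of 38 tested members were not called (adjusted over the list alone, 10 rose and 2 fell). Its igfbp1a and the autophagy receptor sqstm1 (1.46 ± 0.20) rose and pck2, of gluconeogenesis, fell (-0.95 ± 0.12). Without members shared with another list that call ended (adjusted p = 0.697; range over leaving out single libraries 0.00247 to 0.0174).

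Lipid synthesis and storage lists were called higher with the preset correlation. For cholesterol synthesis and Srebf2 targets 6 rose, 3 fell and 19 of 28 tested members were not called (adjusted over the list alone, 10 rose and 3 fell), with adjusted p = 4.97e-04, and adjusted p = 0.185 with an estimated correlation. The rate-limiting reductase gene hmgcra rose (1.96 ± 0.32, adjusted p = 0.00119) and fdps, a later step, fell (-0.48 ± 0.10, adjusted p = 0.0118). The fall of fdps was not called with library size only (0.0614) or without mutant replicate 2 (0.0629) or 4 (0.0610), within a range from 6.89e-04. Without mutant replicate 1, 1 member rose and 2 fell. For fatty acid synthesis and desaturation 4 rose, 1 fell and 14 of 19 tested members were not called (adjusted over the list alone, 6 rose and 1 fell), with adjusted p = 0.0181, and adjusted p = 0.151 with an estimated correlation. In it srebf1, the transcription factor of the pathway (1.13 ± 0.11), elovl6, an elongase (2.04 ± 0.24), fads2 (1.88 ± 0.26) and scd (1.95 ± 0.31), both desaturases, rose. The list was not called without mutant replicate 3 (adjusted p = 0.0704; range from 0.00239). In the lipid droplet and lipolysis list 4 rose, 1 fell and 13 of 18 tested members were not called (adjusted over the list alone, 6 rose and 2 fell), with adjusted p = 0.00705, and adjusted p = 0.0702 with an estimated correlation. The lipid droplet coat gene plin2 went from 11.8 ± 4.66 to 98.6 ± 25.6 CPM (3.06 ± 0.29, adjusted p = 3.99e-06), and without mutant replicate 4 the list was not called (0.114; range from 0.00355). Its count of higher members was 1 without sibling replicate 3 or mutant replicate 1, 2 or 4.

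Lists of plasma protein and lipoprotein genes were called lower with the preset correlation only. For hepatic secreted proteins 2 rose, 20 fell and 17 of 39 tested members were not called (adjusted over the list alone, 2 rose and 20 fell), with adjusted p = 9.32e-12, and adjusted p = 0.0702 with an estimated correlation. Among them c9, of complement (-1.25 ± 0.13), serpinf2b, an antiplasmin (-0.70 ± 0.089), tfa, transferrin (-1.11 ± 0.14), and serpina1l, an antiprotease (-1.20 ± 0.16), fell. For apolipoproteins and lipoprotein assembly 1 rose, 6 fell and 24 of 31 tested members were not called (adjusted over the list alone, 6 rose and 11 fell), with adjusted p = 0.0169, and adjusted p = 0.185 with an estimated correlation, or 0.0524 without sibling replicate 1 (range from 0.0132). The lipid carriers apobb.2 (-1.66 ± 0.20), apoc2 (-1.17 ± 0.14), apom (-0.80 ± 0.11) and apoc1 (-0.76 ± 0.10) fell. For yolk syncytial layer markers 2 rose, 4 fell and 12 of 18 tested members were not called (adjusted over the list alone, 2 rose and 10 fell), with adjusted p = 0.0206, and adjusted p = 0.0908 with an estimated correlation. The genes tfa, rbp4, a retinol carrier (-1.50 ± 0.23), and slc40a1, an iron exporter (-0.65 ± 0.11), fell and creb3l3a rose. That call ended without members shared with another list (adjusted p = 0.684; leaving out single libraries 0.0147 to 0.0409). For retinoid metabolism and signalling 1 rose, 5 fell and 21 of 27 tested members were not called (adjusted over the list alone, 1 rose and 5 fell), with adjusted p = 0.0180, and adjusted p = 0.0737 with an estimated correlation. The retinol binder rbp2b fell (-1.88 ± 0.28) and stra6l rose. Its median of -0.069 turned to 0.033 with library size only, and its call ended without shared members (0.0514) or mutant replicate 4 (0.0669; range from 0.00289).

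Lists of mitochondrial energy genes and ribosome assembly genes were called lower as well, and only the call of oxidative phosphorylation held with an estimated correlation. For nuclear-encoded oxidative phosphorylation 16 fell and 68 of 84 tested members were not called (adjusted over the list alone, 41 fell), and the call held with an estimated correlation (adjusted p = 1.49e-14 and 0.0202). The ATP synthase subunits atp5f1e (-0.50 ± 0.085) and atp5f1b (-0.42 ± 0.073) fell. The 16 called members were 5 with library size only, 7 without sibling replicate 2, and 5 without sibling replicate 3 or mutant replicate 1, 2 or 4. For fatty acid oxidation and Ppar targets 1 rose, 8 fell and 31 of 40 tested members were not called (adjusted over the list alone, 1 rose and 11 fell), with adjusted p = 5.04e-04, and adjusted p = 0.287 with an estimated correlation. Here acsl1b, which activates fatty acids (-1.11 ± 0.11), angptl4, an inhibitor of lipoprotein lipase (-0.95 ± 0.16), and cpt1ab, which brings fatty acids into mitochondria (-0.65 ± 0.12), fell and plin2 rose. Without sibling replicate 2 or mutant replicate 4, 4 members fell. For ribosome biogenesis 9 fell and 27 of 36 tested members were not called (adjusted over the list alone, 29 fell), with adjusted p = 1.70e-13, and adjusted p = 0.184 with an estimated correlation. The gene gar1, which guides ribosomal RNA modification, fell (-0.53 ± 0.10), and 1 member was called without sibling replicate 2 or mutant replicate 1, 3 or 4. For the cell cycle 2 fell and 33 of 35 tested members were not called (adjusted over the list alone, 11 fell), with adjusted p = 9.24e-07, and adjusted p = 0.338 with an estimated correlation, and 0.0520 by fry. The genes mcm5, of DNA replication (-0.39 ± 0.10, adjusted p = 0.0391; range 0.00265 to 0.132), and tyms, which makes thymidylate (-0.41 ± 0.11, adjusted p = 0.0499; range 0.0120 to 0.169), each lost the call without any single library of the stage except sibling replicate 1, and with library size only. The call of tyms was also lost with RLE size factors (0.0531), no low-count filter (0.0687), a CPM filter (0.0625) and without both libraries of low mitochondrial share (0.0933). Cytosolic ribosomal proteins were called lower as a list (adjusted p = 1.49e-07, and adjusted p = 0.384 with an estimated correlation, 0.0686 by fry). Of their 83 members edgeR called 0, over all genes or adjusted over the list alone, and limma-voom 0. At an unadjusted p under 0.05 29 were lower, and DESeq2 called 3 lower.

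Other lists were not called at 24 hpf. For Hnf4 and endodermal transcription factors 1 rose, 1 fell and 20 of 22 tested members were not called (adjusted over the list alone, 2 rose and 3 fell) (adjusted p = 0.0703, or 0.0304 without sibling replicate 4). The gene nr0b2a, a repressor of bile acid synthesis, fell (-1.64 ± 0.10, adjusted p = 4.08e-08). For lipoprotein uptake and lipid transport 4 rose, 5 fell and 25 of 34 tested members were not called (adjusted over the list alone, 6 rose and 8 fell) (adjusted p = 0.886). The lipoprotein receptor lrp1aa (0.95 ± 0.085) and the fatty acid transporter slc27a1b (1.41 ± 0.27) rose, and npc2, a lysosomal cholesterol carrier (-1.70 ± 0.12), and scarb1, a lipoprotein receptor (-0.88 ± 0.16), fell. For lysosome and autophagy 3 rose, 7 fell and 25 of 35 tested members were not called (adjusted over the list alone, 7 rose and 11 fell) (adjusted p = 0.213). The proteases ctsc (-1.60 ± 0.13) and ctsba (-1.16 ± 0.11) fell. For the Igf and growth hormone axis 1 rose, 1 fell and 25 of 27 tested members were not called (adjusted over the list alone, 3 rose and 1 fell) (adjusted p = 0.491).

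In the stress and tissue lists few members were called. For Nrf2 and antioxidant genes 3 fell and 23 of 26 tested members were not called (adjusted over the list alone, 3 rose and 7 fell) (adjusted p = 0.0799). For heat shock 2 fell and 22 of 24 tested members were not called (adjusted over the list alone, 2 fell) (adjusted p = 0.490). For hypoxia and glycolysis 1 rose, 2 fell and 34 of 37 tested members were not called (adjusted over the list alone, 1 rose and 3 fell) (adjusted p = 0.886), and for p53 targets 1 rose, 1 fell and 16 of 18 tested members were not called (adjusted over the list alone, 1 rose and 1 fell) (adjusted p = 0.164). For myeloid cells and inflammation 2 rose and 24 of 26 tested members were not called (adjusted over the list alone, 3 rose) (adjusted p = 0.281). For neurons and glia 1 rose, 1 fell and 32 of 34 tested members were not called (adjusted over the list alone, 1 rose and 1 fell) (adjusted p = 0.715). A single member fell in each of the lists of photoreceptors and lens (33 tested), hatching gland (8), pancreas and intestine (23) and epidermis and ionocytes (34), with adjusted p-values of 0.793, 0.339, 0.954 and 0.1203. Adjusted over the list alone, these lists had 1, 1, 1 and 0 members that fell and hatching gland 1 that rose.

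Both edgeR and limma-voom called 0 members in the lists of mitochondrially encoded genes, skeletal muscle, heart muscle, endothelium, erythroid cells, pigment cells, cartilage, bone and matrix, and the circadian clock. Their adjusted p-values were 0.0703, 0.545, 0.3002, 0.0703, 0.842, 0.0703, 0.886 and 0.3002, in that order. These lists had 12, 42, 15, 31, 22, 24, 37 and 34 members tested and 0 called adjusted over the list alone. At an unadjusted p under 0.05 they had 0, 2, 3, 3, 1, 4, 3 and 5 members, and DESeq2 called 1 pigment cell, 2 cartilage and 3 clock genes higher. Endothelium was called higher with library size only (0.0176), without sibling replicate 2 (0.0355) or mutant replicate 3 (0.0256) and without both libraries of low mitochondrial share (0.0247). Mitochondrially encoded genes were called higher without sibling replicate 1 (0.0123) or 4 (0.0174). Pigment cells were called higher with library size only (0.0348) and without sibling replicate 3 (0.0211) or 4 (0.0184) or mutant replicate 1 (0.0287) or 2 (0.0171). Skeletal muscle was called lower without sibling replicate 1 (0.0147) and erythroid cells higher without mutant replicate 1 (0.0250). Without members shared with another list, hatching gland genes were called higher (0.0439) and Nrf2 genes lower (0.0470). The signs of median, mean and test differed for lipoprotein uptake (median 0.024, mean -0.025, test down) and for the hatching gland (median 0.21, mean -0.10, test up). They also differed for photoreceptors (median -0.081, mean 0.041, test up), for the Igf axis (median -0.044, mean 0.02, test up), for pancreas and intestine (median -0.16, test up) and for cartilage (median -0.059, mean 0.068, test down).

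Sibling replicate 2 at 24 hpf had 0.847% of its counts in mitochondrially encoded genes, against 1.27% to 1.90% in the other siblings. Without it 263 genes were called higher and 317 lower. The lower genes were also fewer without sibling replicate 3 (343) and without mutant replicates 1 (291), 2 (315), 3 (320) and 4 (258). Without that sibling and sibling replicate 3 at 48 hpf together, 488 were called higher and 646 lower.

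At 48 hpf the mutants had more RNA of genes of cholesterol synthesis, lipid droplets, heat shock and targets of Atf4, list calls that held with an estimated correlation. With the preset correlation only, lists of fatty acid synthesis, ER stress and lipoprotein assembly were called higher, and lists of muscle, neurons, photoreceptors, cartilage and fatty acid oxidation lower. There 1040 genes were called higher and 440 lower, of which 427 and 128 changed at least 2-fold. The share of called genes that were higher was 70.27%, and 59.7% with DESeq2.

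Of the genes that met the naming rule, isg15 again had the greatest rise, from 0.0623 ± 0.0610 to 30.5 ± 8.77 CPM (8.99 ± 0.52, adjusted p = 3.74e-08). The gene arf4b, a small GTPase of the Golgi, rose from 0.147 ± 0.127 to 44.7 ± 16.01 CPM (8.35 ± 0.49, adjusted p = 3.74e-08). The gene tm4sf4, a membrane protein of gut and liver, rose by 5.55 ± 0.56, chia.6, a chitinase, by 5.21 ± 0.70, irf1b, a transcription factor of the interferon pathway, by 5.14 ± 0.56, and hal, which breaks down histidine, by 4.67 ± 0.76. Both fep15 (4.86 ± 0.43) and tmem86b (4.84 ± 0.40), which also rose at 24 hpf, were among the genes with the greatest rise. The genes cd83, a surface protein of immune cells, slc28a1, a nucleoside transporter, and tnip2, which restrains NF-kB signalling, rose by 4.50, 4.14 and 4.08. The gene leap2, a liver peptide that blocks the ghrelin receptor, rose by 4.15 ± 0.78, adjusted p = 0.00283, but its adjusted p was 0.0569 with DESeq2 (range from 4.55e-05).

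By the same rule slc10a1, the bile acid transporter, fell the most (-4.20 ± 0.34, adjusted p = 8.61e-07). The genes gnb3a, a G protein subunit of cone photoreceptors (-3.79 ± 0.56), lect2l, a secreted leukocyte attractant (-3.71 ± 0.45), soat2, which esterifies cholesterol (-3.17 ± 0.53), and apobb.2, an apolipoprotein B gene (-3.11 ± 0.25), fell. So did ccdc88aa, an actin-binding signal protein (-2.92), rbp2b, a cellular retinol binder (-2.90), sardh (-2.77), cfhl1 (-2.74), akr1a1a (-2.73) and sfrp1b, a secreted Wnt inhibitor (-2.63). The cathepsin gene ctsll, a marker of hatching gland and yolk layer, fell by 3.44 (adjusted p = 9.50e-04). It was not called by limma-voom (0.0821) or with the libraries of the stage alone (0.0885), within a range of 8.12e-05 to 0.107.

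Of the genes fixed for naming, creb3l3a (1.08 ± 0.17, adjusted p = 5.50e-04), igfbp1a (1.39 ± 0.18, adjusted p = 9.91e-05) and hmgcs1 (1.16 ± 0.15, adjusted p = 7.14e-05) rose. The gene apoba fell (-0.73 ± 0.16, adjusted p = 0.00783), with an adjusted p of 0.0568 without mutant replicate 1 (range from 7.47e-05). The genes hnf4a (0.19), apobb.1 (0.12), apoa1b (-0.26), igf1 (-0.37), igf2b (0.35) and flt1 (0.26) were not called, with adjusted p-values from 0.158 to 0.792. The gene pla2g12b was not called (0.48 ± 0.18, adjusted p = 0.144; range 3.59e-05 to 0.354) but rose without sibling replicate 3 (adjusted p = 1.03e-04). The lipoprotein receptor gene ldlra was not called (1.08 ± 0.38, adjusted p = 0.118; range 0.00106 to 0.339), whereas DESeq2 (0.0276), limma-voom (0.00106) and the libraries of the stage alone (0.0128) called it higher.

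Stress lists were called higher, and the calls of Atf4 targets and of heat shock held with an estimated correlation. For Atf4 targets 21 rose and 17 of 38 tested members were not called (adjusted over the list alone, 27 rose and 1 fell) (adjusted p = 6.43e-16 and 0.00404). The genes ddit3 (2.62 ± 0.17) and the serine synthesis genes psat1 (1.41 ± 0.13) and phgdh (0.91 ± 0.10) rose. For heat shock, the cytosolic chaperones, 7 rose and 17 of 24 tested members were not called (adjusted over the list alone, 11 rose) (adjusted p = 7.88e-07 and 0.00404). The genes hsp90aa1.1 (1.49 ± 0.15) and hsp70.3 (1.86 ± 0.34) rose. For ER stress 14 rose and 16 of 30 tested members were not called (adjusted over the list alone, 18 rose), with adjusted p = 5.88e-13, and adjusted p = 0.0657 with an estimated correlation. The genes hspa5 (1.35 ± 0.12) and dnajb9b (3.15 ± 0.30) rose. For Nrf2 and antioxidant genes 7 rose and 19 of 26 tested members were not called (adjusted over the list alone, 7 rose), with adjusted p = 0.00238, and adjusted p = 0.0915 with an estimated correlation. The redox protein txn (1.76 ± 0.21), the haem oxygenase hmox1a (1.0999 ± 0.14) and gclc, of glutathione synthesis (0.70 ± 0.10), rose. For p53 targets 4 rose and 14 of 18 tested members were not called (adjusted over the list alone, 4 rose), with adjusted p = 0.00276, and adjusted p = 0.0915 with an estimated correlation. The p53 inhibitor mdm2 rose (1.55 ± 0.11). For myeloid cells and inflammation 3 rose and 23 of 26 tested members were not called (adjusted over the list alone, 3 rose), with adjusted p = 2.71e-04, and adjusted p = 0.0915 with an estimated correlation. The cytokine receptor il6st (1.16 ± 0.11), stat3 (0.98 ± 0.11) and socs3a (2.36 ± 0.39), which signal inside many cell types, rose. For fasting and Foxo targets 7 rose, 1 fell and 30 of 38 tested members were not called (adjusted over the list alone, 8 rose and 3 fell), with adjusted p = 0.0215, and adjusted p = 0.0657 with an estimated correlation. The gene trim63a, a ubiquitin ligase of muscle wasting, rose (0.95 ± 0.12) and pdk4, which shuts off pyruvate oxidation, fell (-1.25 ± 0.16). That call ended without sibling replicate 1 (0.0789) or mutant replicate 2 (0.0568; range 0.0129 to 0.0789).

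Lipid lists were called higher, and the calls of cholesterol synthesis and of lipid droplets held with an estimated correlation. For cholesterol synthesis and Srebf2 targets 14 rose and 14 of 28 tested members were not called (adjusted over the list alone, 21 rose) (adjusted p = 4.31e-13 and 0.0212). The genes cyp51 (1.37 ± 0.13), hmgcra (1.89 ± 0.34) and insig1, the sensor of the pathway (1.42 ± 0.18), rose. For lipid droplet and lipolysis 7 rose and 11 of 18 tested members were not called (adjusted over the list alone, 7 rose and 1 fell) (adjusted p = 0.00238 and 0.0465). The lipases lipg (1.69 ± 0.16) and lpl (1.57 ± 0.16) and plin2 (2.44 ± 0.33) rose. For fatty acid synthesis and desaturation 7 rose, 1 fell and 11 of 19 tested members were not called (adjusted over the list alone, 7 rose and 2 fell), with adjusted p = 0.0156, and adjusted p = 0.0925 with an estimated correlation. The genes srebf1 (2.07 ± 0.13), scd (3.65 ± 0.37), fads2 (2.404 ± 0.28) and acaca, the first enzyme of the pathway (0.97 ± 0.11), rose, and the list median of 0.053 was -0.019 without mutant replicate 2. For apolipoproteins and lipoprotein assembly 13 rose, 4 fell and 14 of 31 tested members were not called (adjusted over the list alone, 16 rose and 5 fell), with adjusted p = 4.40e-04, and adjusted p = 0.0657 with an estimated correlation. The genes apoa4b.2, a plasma apolipoprotein (2.47 ± 0.27), cideb, which loads lipid on lipoproteins (1.77 ± 0.24), and creb3l3b (1.78 ± 0.25) rose, while apobb.2, apoba and soat2 fell. For lipoprotein uptake and lipid transport 10 rose, 4 fell and 20 of 34 tested members were not called (adjusted over the list alone, 12 rose and 5 fell), with adjusted p = 0.0189, and adjusted p = 0.0657 with an estimated correlation. The genes abca1b, a cholesterol exporter (0.94 ± 0.12), and mfsd2ab, a transporter of lysolipids (0.74 ± 0.10), rose. Without sibling replicate 2 the list was not called (0.0794; range from 0.00518), with 5 members higher and 5 lower.

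For Hnf4 and endodermal transcription factors 4 rose, 2 fell and 16 of 22 tested members were not called (adjusted over the list alone, 6 rose and 2 fell), with adjusted p = 0.0480, and adjusted p = 0.242 with an estimated correlation. The genes hnf4b (0.96 ± 0.17) and gata6 (1.05 ± 0.12) rose and prox1a, of liver and lens (-0.85 ± 0.11), and nr0b2a (-0.63 ± 0.12) fell. The call ended with library size only (0.0542), without shared members (0.350), without sibling replicate 3 (0.0889) or mutant replicate 2 (0.106; range from 0.0332), and without both libraries of low mitochondrial share (0.0896). For the hatching gland, whose enzymes digest the egg envelope, 3 rose, 1 fell and 4 of 8 tested members were not called (adjusted over the list alone, 4 rose and 1 fell) (adjusted p = 0.00132, which held at 0.0465 with an estimated correlation). The genes cd63 (0.99 ± 0.089), ctslb (1.097 ± 0.13) and he1.1 (0.56 ± 0.084) rose and ctsll fell. The median of the list was 0.41 and the mean 0.069, and the mean log2 CPM of its genes overlapped between mutants (4.08 to 4.52) and siblings (4.06 to 4.56). For lysosome and autophagy 8 rose, 1 fell and 26 of 35 tested members were not called (adjusted over the list alone, 14 rose and 2 fell), with adjusted p = 4.40e-04, and adjusted p = 0.136 with an estimated correlation. The genes sqstm1 (1.68 ± 0.23), ctsz (0.97 ± 0.14) and ctsc (0.76 ± 0.15) rose, and 4 members rose without mutant replicate 1. For the endothelium 3 rose, 1 fell and 27 of 31 tested members were not called (adjusted over the list alone, 6 rose and 1 fell), with adjusted p = 0.00148, and adjusted p = 0.0915 with an estimated correlation. The scavenger receptor gene stab2 rose (0.61 ± 0.12, adjusted p = 0.00465; range 3.42e-04 to 0.0772), a call lost with the libraries of the stage alone. For ribosome biogenesis 3 rose and 33 of 36 tested members were not called (adjusted over the list alone, 9 rose), with adjusted p = 6.68e-06, and adjusted p = 0.294 with an estimated correlation. The large-subunit assembly gene bop1 rose (0.54 ± 0.12, adjusted p = 0.00884). Cytosolic ribosomal proteins were called higher as a list (adjusted p = 7.77e-05, and adjusted p = 0.418 with an estimated correlation), but not by fry (0.0929) or without sibling replicate 2 (0.0520; range from 5.62e-08). Of the members, edgeR called 0 of 83 members, over all genes or adjusted over the list alone. At an unadjusted p under 0.05 25 were higher, and DESeq2 called 2 and limma-voom 3.

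Tissue lists and fatty acid oxidation were called lower at 48 hpf with the preset correlation, and none of these calls held with an estimated one. For skeletal muscle 7 fell and 35 of 42 tested members were not called (adjusted over the list alone, 16 fell), with adjusted p = 1.42e-09, and adjusted p = 0.207 with an estimated correlation. The genes acta1b, an actin (-0.95 ± 0.15), and atp2a1, the calcium pump of muscle (-0.68 ± 0.13), fell, and 4 members fell without sibling replicate 3. For neurons and glia 1 rose, 9 fell and 24 of 34 tested members were not called (adjusted over the list alone, 1 rose and 15 fell), with adjusted p = 3.92e-07, and adjusted p = 0.0915 with an estimated correlation. The gene stmn2b, of growing axons, fell (-0.45 ± 0.10, adjusted p = 0.00915; range 1.76e-04 to 0.0684), a call lost without mutant replicate 3 and with the libraries of the stage alone, and nefma, a neurofilament, rose (1.305 ± 0.28). The 9 members of that list that fell were 3, 2 and 0 without mutant replicates 1, 2 and 3, and 5 without sibling replicate 3. For photoreceptors and lens 3 fell and 30 of 33 tested members were not called (adjusted over the list alone, 3 fell), with adjusted p = 0.00831, and adjusted p = 0.372 with an estimated correlation, 0.226 by fry and 0.0822 without sibling replicate 2 (range from 7.24e-04). The photoreceptor transcription factors crx (-1.75 ± 0.23) and otx5 (-1.65 ± 0.26) fell. For cartilage, bone and matrix 4 fell and 33 of 37 tested members were not called (adjusted over the list alone, 2 rose and 6 fell), with adjusted p = 0.00202, and adjusted p = 0.163 with an estimated correlation, and 2 members fell without sibling replicate 3. For fatty acid oxidation and Ppar targets 3 rose, 12 fell and 25 of 40 tested members were not called (adjusted over the list alone, 5 rose and 17 fell), with adjusted p = 1.39e-05, and adjusted p = 0.125 with an estimated correlation. Both pdk4 and hadhb, of mitochondrial fat breakdown (-0.63 ± 0.092), fell and the nuclear receptor pparab rose (0.99 ± 0.15), and 6 members fell without mutant replicate 1. Oxidative phosphorylation was called lower as a list (adjusted p = 0.00148, and adjusted p = 0.161 with an estimated correlation) with 0 of 84 members called by edgeR, over all genes or adjusted over the list alone. At an unadjusted p under 0.05 16 were lower, and DESeq2 called 5 and limma-voom 1.

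The remaining lists were not called at 48 hpf. For hepatic secreted proteins 9 rose, 9 fell and 21 of 39 tested members were not called (adjusted over the list alone, 11 rose and 10 fell) (adjusted p = 0.455). The plasma proteins fetub (-1.92 ± 0.16), tfa (-2.08 ± 0.17) and serpina1l (-2.14 ± 0.19) fell, and the complement factor cfb rose (1.61 ± 0.15). For yolk syncytial layer markers 5 rose, 2 fell and 11 of 18 tested members were not called (adjusted over the list alone, 7 rose and 3 fell) (adjusted p = 0.212; median 0.25, mean -0.064). For retinoid metabolism and signalling 2 rose, 2 fell and 23 of 27 tested members were not called (adjusted over the list alone, 4 rose and 3 fell) (adjusted p = 0.833). For the Igf and growth hormone axis 3 rose, 1 fell and 23 of 27 tested members were not called (adjusted over the list alone, 3 rose and 1 fell) (adjusted p = 0.114). The gene igfbp2a, a binder of insulin-like growth factors, fell (-0.85 ± 0.13). For hypoxia and glycolysis 4 rose, 1 fell and 32 of 37 tested members were not called (adjusted over the list alone, 5 rose and 4 fell) (adjusted p = 0.867). For the circadian clock 2 rose and 32 of 34 tested members were not called (adjusted over the list alone, 2 rose) (adjusted p = 0.0804). For pancreas and intestine 1 rose, 2 fell and 20 of 23 tested members were not called (adjusted over the list alone, 1 rose and 2 fell) (adjusted p = 0.751), and for the cell cycle 1 rose and 34 of 35 tested members were not called (adjusted over the list alone, 1 rose) (adjusted p = 0.0610). For heart muscle 1 rose and 14 of 15 tested members were not called (adjusted over the list alone, 1 rose) (adjusted p = 0.928), and for pigment cells 1 fell and 23 of 24 tested members were not called (adjusted over the list alone, 1 fell) (adjusted p = 0.0948). The cell cycle list was called higher without sibling replicate 3 (5.04e-06) or mutant replicate 1 (0.00305), without both libraries of low mitochondrial share (9.49e-06) and with library size only (0.0203). The circadian clock was called higher without sibling replicate 2 (0.0284) or mutant replicate 1 (0.0188) and by fry (0.0480), and hepatic secreted proteins lower without mutant replicate 1 (0.0478). By fry, yolk layer markers (2.16e-04) and the Igf axis (1.62e-04) were called higher.

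No members were called by edgeR in the lists of mitochondrially encoded genes (12 tested), erythroid cells (22) and epidermis and ionocytes (34), over all genes or adjusted over the list alone (camera adjusted p = 0.629, 0.326 and 0.928). At an unadjusted p under 0.05 they had 0, 3 and 4 members. DESeq2 called 0, 1 and 2 of them and limma-voom 0, 1 and 3. The median of mitochondrially encoded genes, 0.093, was -0.28 without sibling replicate 3, and the list was then called lower (adjusted p = 0.0464). That library had 0.696% of its counts in mitochondrially encoded genes, against 1.71% and 1.80% in the other siblings, and counts in 23327 genes against 26890 and 26948. Its mean log2 CPM of hatching gland genes (4.56) and of cell cycle genes (6.20) lay above that of the other siblings (4.06 and 4.17, and 5.83 and 5.92) and of every mutant (at most 4.52 and 6.19). Without it 1058 genes were called higher and 388 lower. Without both libraries of low mitochondrial share the counts were 1157 and 701, and leaving out mutant replicate 1, 2 or 3 gave 220, 250 or 207 lower genes.

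**Figure D2:**
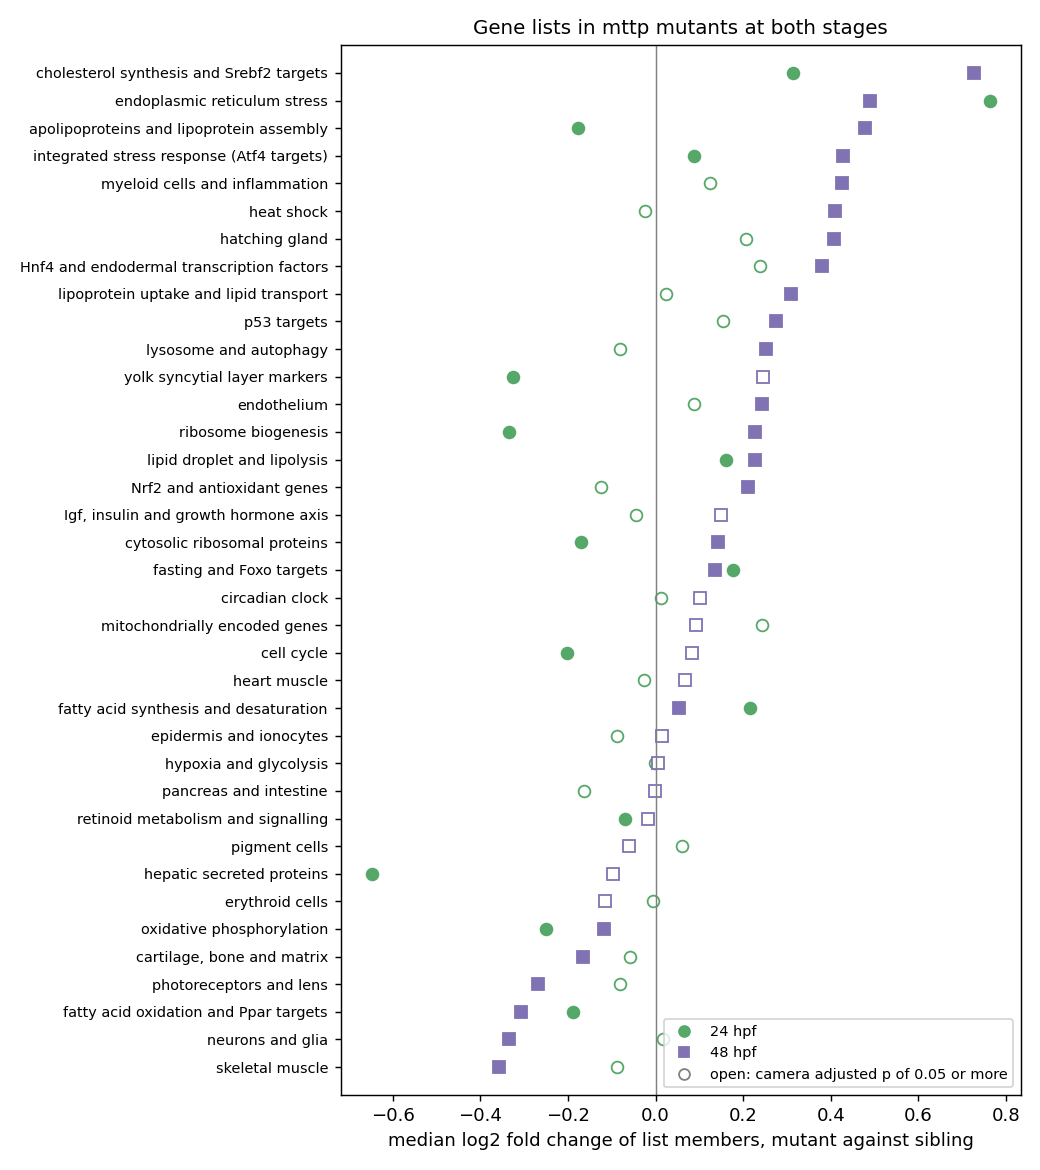
Median log2 fold change of mutants against siblings (x axis) over the tested members of each of 37 gene lists (y axis), at 24 hpf (green circles) and 48 hpf (purple squares); open symbols are lists with a camera adjusted p of 0.05 or more with the preset correlation. ER stress genes had the highest median at 24 hpf (0.76) and cholesterol synthesis at 48 hpf (0.73), and hepatic secreted proteins the lowest at 24 hpf (-0.65); library size only turned the sign of the retinoid median at both stages.

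The mutants' response differed between the stages: the mutant effect on lists of lipoprotein assembly genes, Atf4 targets and heat shock genes was more positive at 48 hpf. The list of ER stress genes was less positive there with the preset correlation only (adjusted p = 0.126 with an estimated correlation). The difference was tested as an interaction, which called 594 genes with a more positive and 180 with a more negative mutant effect at 48 hpf (76.7% more positive, 63.3% with DESeq2, 66.7% with library size only and 65.0% with a CPM filter). Without single libraries the more positive genes were 387 (mutant replicate 3 at 24 hpf), 342 (mutant replicate 4 at 24 hpf) or 1053 (sibling replicate 3 at 48 hpf). The more negative ones were 109, 375, 89 and 88 without sibling replicates 2 and 3 and mutant replicates 1 and 3 at 48 hpf. Stage and the batch label coincide, so a batch effect on the response cannot be told apart from stage. The cathepsin gene ctss2.1 fell at 24 hpf but measured 16.2 ± 3.01 CPM in mutants and 3.68 ± 1.04 in siblings at 48 hpf (difference 5.20 ± 0.38, adjusted p = 1.98e-06). The gene slc25a38a, a mitochondrial glycine carrier, differed by 5.39 ± 0.50, adjusted p = 1.65e-05, and slc28a1 (4.43 ± 0.55) and tnip2 (4.44 ± 0.80) were also more positive. Both arf4b (5.29 ± 0.65; adjusted p 1.04e-16 to 0.106 over the alternatives) and cd83 (4.57 ± 0.74; 7.25e-08 to 0.0660) lost their call with limma-voom.

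Among genes that met the rule, clstn3 had the most negative difference (-4.07 ± 0.24, adjusted p = 2.24e-07), followed by gnb3a (-3.78 ± 0.85, adjusted p = 0.0205; range 0.00398 to 0.261). The call of gnb3a was lost with limma-voom, without mutant replicate 2 (0.0730) or 4 (0.0638) at 24 hpf, and without sibling replicate 2 (0.0647), mutant replicate 1 (0.0515) or mutant replicate 3 (0.0574) at 48 hpf. The genes phka1b, of glycogen breakdown (-2.85 ± 0.53), and tmppe, a phosphoesterase (-2.76 ± 0.29), were more negative as well. Both ush1c (-2.57 ± 0.53; range 9.92e-05 to 0.0705) and crx (-2.51 ± 0.36; range 5.80e-09 to 0.0618) lost their call with limma-voom. Camera called 15 lists more positive and 6 more negative. With an estimated correlation 3 of these held, all more positive. For apolipoproteins and lipoprotein assembly 11 were more positive, 1 more negative and 19 of 31 tested members were not called (adjusted over the list alone, 14 were more positive and 2 more negative) (adjusted p = 0.0376 with an estimated correlation). For Atf4 targets 11 were more positive and 27 of 38 tested members were not called (adjusted over the list alone, 21 were more positive and 2 more negative) (adjusted p = 0.0376 with an estimated correlation). For heat shock 6 were more positive and 18 of 24 tested members were not called (adjusted over the list alone, 11 were more positive) (adjusted p = 0.00594 with an estimated correlation).

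The calls of both stages overlapped more than chance gives. In all 191 genes were higher at both stages (15.6 expected, one-sided Fisher's exact p = 2.27e-164) and 71 lower at both (10.23 expected, one-sided Fisher's exact p = 9.21e-39). Another 47 were lower at 24 and higher at 48 hpf (24.2 expected, one-sided Fisher's exact p = 1.21e-05), and 1 was higher at 24 and lower at 48 hpf (6.59 expected, one-sided Fisher's exact p = 0.999). Genes are not independent replicates. Across all tested genes the correlation of the changes was weak (Pearson's r = 0.17, Spearman's rho = 0.13, across genes). Of 2104 genes called at either stage, 63.4% changed in the same direction at both.

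Between 24 and 48 hpf the siblings raised genes of neurons and lowered genes of the hatching gland, list calls that held with an estimated correlation. Lists of lens, muscle, cartilage and pigment genes were higher and lists of cell division and ribosome genes lower with the preset correlation only. In siblings 6388 genes were called higher and 6419 lower at 48 hpf. The lens crystallins crygm2d15 (at least 3159-fold), crygm2d9 (at least 3141-fold), crygm2d11 (at least 444-fold) and crygmxl1 (at least 305-fold) and the lens membrane protein lim2.5 (at least 399-fold) were higher, against a floor of 3 counts over the 24 hpf siblings, which had 0. Reads can be shared among members of the crystallin family. The gene col10a1a, a collagen of bone-forming cells, had 2 counts over the 24 hpf siblings and 42.7 ± 6.90 CPM at 48 hpf. The gene her1, an oscillating gene of somite formation, was at least 175-fold lower, against the same floor over the 48 hpf siblings. The gene he1.3, a hatching enzyme, fell by 7.17, znfl1h, a zinc finger gene, by 6.72, ctss2.1 by 6.28, ctslb by 5.37 and abcb11a, a bile salt exporter, by 4.90, each with an adjusted p of at most 4.85e-08.

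Camera called 6 lists higher and 5 lower at 48 hpf in siblings. Neurons and glia (32 higher and 1 lower of 34 members; adjusted over the list alone 32 and 1) and the hatching gland (0 higher and 7 lower of 8; adjusted over the list alone 0 and 7) kept their calls with an estimated correlation (adjusted p = 0.0296 and 0.0296). Higher with the preset correlation only were photoreceptors and lens (27 higher and 2 lower of 33), skeletal muscle (39 higher and 1 lower of 42), cartilage, bone and matrix (28 higher and 3 lower of 37), hypoxia and glycolysis (25 higher and 5 lower of 37) and pigment cells (19 higher and 4 lower of 24), with adjusted p-values from 0.143 to 0.256 with an estimated correlation. Lower with the preset correlation only were the cell cycle (0 higher and 35 lower of 35), ribosome biogenesis (0 higher and 35 lower of 36), cytosolic ribosomal proteins (0 higher and 79 lower of 83) and yolk syncytial layer markers (3 higher and 10 lower of 18), with 0.143 to 0.173 with an estimated correlation. Adjusted over the list alone, the members higher and lower were 27 and 2 for photoreceptors, 39 and 2 for muscle, 28 and 3 for cartilage, 27 and 5 for hypoxia, 19 and 4 for pigment cells, 0 and 35 for the cell cycle, 0 and 35 for ribosome biogenesis, 0 and 81 for ribosomal proteins and 3 and 11 for yolk layer markers. For fatty acid oxidation, the Igf axis and fasting targets, which were not called, higher members outnumbered lower ones (13 higher and 7 lower of 40, 13 higher and 4 lower of 27 and 13 higher and 8 lower of 38), and for apolipoproteins lower members did (7 higher and 14 lower of 31).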

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

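The tests of a library of low mitochondrial share, of the genes beside mttp, of a slope with no sibling library in both changes and of other splits of the libraries for the stage difference and for sibling development were chosen only after the results were seen.

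In 7 of 170 groups of 4 libraries 1 library lay far from the other 3 by Dixon's test, where chance flags about 1 in 20 groups (8.5 expected). At 24 hpf these were CPM of 92.7 for angptl4 in sibling replicate 3 (the others averaged 63.7), 1903 for apoa1b in mutant replicate 2 (2162) and 37.1 for elovl6 in sibling replicate 1 (16.8). For hspa5 sibling replicate 3 had 443 CPM (361), for hyou1 mutant replicate 1 had 536 (444), for tfa sibling replicate 2 had 2442 (1778) and for tyms sibling replicate 1 had 45.0 (54.1).

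The mutant effect differed between the stages, by the interaction test, in 77 of 143 named genes and 21 of 37 lists. Many genes were named for large changes in the same fits, which raises that share; of all 24424 genes tested, 774 (3.17%) differed. Each value is the log2 fold change at 48 hpf minus that at 24 hpf. Genes of lipoproteins and lipid transport became more positive: abca1b (1.15), apoa4b.2 (1.85), apoc2 (1.06), apom (1.41), cideb (1.66), creb3l3b (1.22), lipg (1.26), lpl (1.03), npc2 (1.11), pla2g12a (1.12), pla2g12b (0.98) and scarb1 (1.71). The exceptions were apobb.2 (-1.45) and lrp1aa (-1.15). Lipid synthesis and oxidation differed in acaca (0.74), acsl1b (0.90), cpt1ab (0.67), cyp51 (1.16), fdps (1.13), pparab (0.81), srebf1 (0.94) and pdk4 (-1.39). Stress and signalling genes more positive at 48 hpf were ddit3 (1.52), gclc (0.66), hmox1a (1.54), hsp70.3 (1.74), hsp90aa1.1 (1.71), mdm2 (1.42), phgdh (1.104), psat1 (0.80), slc3a2a (1.41), trim63a (0.97), txn (2.46), pck2 (1.89), il6st (0.90), socs3a (2.1999), stat3 (0.57) and irf1b (3.00). Genes of the ER rose less at 48 hpf: derl3 (-1.61), dnajc3a (-1.13), hsp90b1 (-1.89) and hyou1 (-1.06). Transcription factors of endoderm and of photoreceptors differed in gata6 (0.66), hnf4b (1.03), nr0b2a (1.01), prox1a (-1.09), crx (-2.51) and otx5 (-1.79). Plasma proteins differed in cfb (1.58), fetub (-1.25), serpina1l (-0.94), serpinf2b (1.00) and tfa (-0.96). Lysosomal and hatching gland proteases and cd63 differed in cd63 (0.75), ctsba (1.52), ctsc (2.36), ctslb (1.02), ctss2.1 (5.20) and ctsz (1.28). The growth genes were bop1 (0.82), gar1 (0.71) and mcm5 (0.64). Other genes more positive were arf4b (5.29), cd83 (4.57), cyp1c1 (2.63), dao.1 (2.09), slc25a38a (5.39), slc28a1 (4.43) and tnip2 (4.44), and others more negative were clstn3 (-4.07), gnb3a (-3.78), phka1b (-2.85), pmt (-1.69), sfrp1b (-1.76), slc10a1 (-1.60), tmppe (-2.76) and ush1c (-2.57).

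With an estimated correlation only 3 of the 21 lists kept their call, apolipoproteins, Atf4 targets and heat shock. Among lists, the median differences were 0.58 for ribosome biogenesis, 0.55 for yolk syncytial layer markers, 0.54 for heat shock, 0.45 for cholesterol synthesis, 0.43 for apolipoproteins and 0.41 for Atf4 targets. They were 0.34 for Nrf2 genes, 0.34 for myeloid cells, 0.33 for lysosome, 0.31 for the cell cycle, 0.305 for cytosolic ribosomal proteins, 0.26 for the hatching gland, 0.25 for hepatic secreted proteins, 0.25 for lipoprotein uptake and 0.16 for oxidative phosphorylation. Lists more negative at 48 hpf were ER stress (-0.44), neurons (-0.37), skeletal muscle (-0.27), pigment cells (-0.22), photoreceptors (-0.14) and cartilage (-0.12). Without shared members the adjusted p was 0.206 for yolk layer markers and 0.203 for uptake, which was also not called without sibling replicate 2 at 48 hpf (0.0637). The calls of oxidative phosphorylation (without sibling replicate 1 at 48 hpf, 0.0552), myeloid cells (sibling replicate 3 at 48 hpf, 0.0632; both libraries of low mitochondrial share, 0.0737), pigment cells (sibling replicate 2 at 24 hpf, 0.0507) and cartilage (sibling replicate 1 at 24 hpf, 0.0797; sibling replicate 3 at 48 hpf, 0.133) were lost without the libraries named. That of photoreceptors was lost without sibling replicate 1 at 24 hpf (0.110), sibling replicate 2 at 24 hpf (0.135), mutant replicate 3 at 24 hpf (0.0991), mutant replicate 4 at 24 hpf (0.0674) or sibling replicate 2 at 48 hpf (0.122) (range from 0.00115), as well as with library size only (0.0665) and without both libraries of low mitochondrial share (0.0737). By fry, the calls of skeletal muscle (0.145), photoreceptors (0.310), pigment cells (0.190) and cartilage (0.145) were lost.

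For the changes at 24 hpf, other splits of the 8 libraries argue against chance: 1 of 35 splits, the real one, called as many genes (934, against 10 at most in the others). A developmental delay was argued against, because the slope of the mutant change on the sibling stage change, corrected for shared sibling libraries, was 0.0450 and not negative (0.0292 to 0.0571 without single libraries; 0.0787 uncorrected). With no sibling library in both changes it was 0.0379 (0.0173 to 0.0592 over 6 ways of dividing the siblings). Mutants simulated without a change gave an uncorrected 0.0211, no baseline because draws around the sibling means left out the siblings' spread. Mutants ahead in stage, as a positive slope allows, stay open. Linkage over the chromosome of mttp was argued against as the whole cause by the share of called genes on its chromosome (35 of 717, one-sided Fisher's exact p = 0.524), and a gene length bias as the whole cause by 91.0% of calls kept after a trend with gene span was taken off, although the correlation with gene span (rho 0.173 across genes) was above the bound of 0.1 set beforehand. Without sibling replicate 2, of low mitochondrial share, 552 of the 934 calls held (580 called). That library may explain part, not all, of the calls. A response to mttp loss, such as ER stress from lipoproteins that cannot be loaded, may explain them, as a hypothesis; a difference in clutch, in RNA handling or in read sharing between similar genes stays open and was not tested.

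For the changes at 48 hpf the 10 splits of 6 libraries are too few for a share under 0.05 (1480 genes in the real split, 0 at most in the others). A developmental delay of the mutants had the negative slope it needs: the corrected slope was -0.100 (-0.119 to -0.0736 without single libraries; -0.180 uncorrected). With no sibling library in both changes it was -0.0800 (-0.110 to -0.0388 over 6 ways of dividing the siblings), and mutants simulated without a change gave -0.0314. Of the lists that change with stage, neurons, muscle, photoreceptors and cartilage were called lower and hatching gland, ribosome biogenesis and cytosolic ribosomal proteins higher. Only the hatching gland held with an estimated correlation, although its library means overlapped. Others were called towards delay by some alternatives only (cell cycle, pigment cells, yolk layer) or by none (hypoxia). Delay may explain part of the tissue genes; it was not tested whether it explains genes of lipid and stress lists that do not follow stage. Linkage over the chromosome of mttp was argued against as the whole cause (54 of 717, one-sided Fisher's exact p = 0.444). So was gene length (rho -0.0936 across genes, 93.5% of calls kept), although taking off the trend with gene span moved the lower genes from 355 to 553 and the higher ones from 843 to 838. Also argued against as the whole cause was sibling replicate 3, of low mitochondrial share. Without it 1446 genes were called and 1130 of the 1480 calls held, against 946 and 905 without mutant replicate 1. A response to mttp loss stays open as a biological explanation, beside clutch and RNA handling, which were not tested.

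For sibling development the real split of 35 called most genes (12807 against 6871), arguing against chance. For the stage difference, inseparable from batch, 50 drawn splits (774 genes, others at most 304) re-dealt genotype within stages. They cannot test equal effects at both stages.

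Genes near mttp were higher in mutants: saraf, a calcium regulator of the ER, by 1.16 at 24 hpf and 1.46 at 48 hpf (adjusted p = 6.94e-05 and 2.34e-05), stra6l, a retinol transporter, by 1.03 and 1.87 (adjusted p = 0.0121 and 1.65e-04), and pla2g12a, a phospholipase relative, by 0.56 and 1.68 (adjusted p = 0.0504 and 1.57e-05). At 24 hpf pla2g12a was called under 9 of 18 alternatives, with adjusted p from 0.00266 to 0.161. At 48 hpf ttyh3b, a channel gene among the 20 nearest, fell by 0.46 (adjusted p = 0.00606). Of the 20 nearest tested genes in RefSeq order, 2 were called at 24 hpf (one-sided Fisher's exact p = 0.227) and 4 at 48 hpf (one-sided Fisher's exact p = 0.0463), so a stretch of chromosome that travels with the mutation may contribute and cannot be told apart from a response of these genes to mttp loss. Of the called genes saraf and ttyh3b were chosen after their values were seen.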

How the results depend on the processing

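The setting without both libraries of low mitochondrial share was chosen only after the data were seen. Counts of called genes moved by over 1.5 times as follows, and the cause was not tested except where named. At 24 hpf the 366 higher genes were 626 with DESeq2, 550 with library size only and 1040 with a replicate block in the libraries of the stage only, and the 568 lower genes were 995, 313 and 1540 with these. A replicate block gave 869 lower genes and the libraries of the stage only 853, while leaving out single libraries gave 258 (without mutant replicate 4) to 480 (without sibling replicate 1). At 48 hpf the 1040 higher genes were 615 with the libraries of the stage only, and the 440 lower genes were 843 with DESeq2, 735 with limma-voom, 701 without both libraries of low mitochondrial share and 207 (without mutant replicate 3) to 417 (without sibling replicate 1) without single libraries. For the difference between stages, the 594 more positive genes ranged from 342 (without mutant replicate 4 at 24 hpf) to 1053 (without sibling replicate 3 at 48 hpf) without single libraries. The 180 more negative genes were 504 with DESeq2, 281 with a CPM of at least 1 in 3 libraries, 311 with a replicate block, 481 without both libraries of low mitochondrial share and 88 (without mutant replicate 3 at 48 hpf) to 375 (without sibling replicate 3 at 48 hpf) without single libraries. Requiring at least a 2-fold change lowers counts by construction: to 154 and 132 at 24 hpf, 427 and 128 at 48 hpf, 288 and 80 for the difference, 4225 and 2347 for sibling development, and 83 and 35 for genes higher or lower at both stages. Genes lower at both stages were 116 with DESeq2. With an estimated correlation the lists called higher and lower were 2 and 1 at 24 hpf (from 6 and 9) and 5 and 0 at 48 hpf (from 18 and 6).

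A pair of list results reversed. Mitochondrially encoded genes at 48 hpf turned from not called and higher to lower without sibling replicate 3 (0.0464, the lowest of 0.0464 to 0.876 without single libraries) and without both libraries of low mitochondrial share (0.00795); that sibling's low share of these genes shows the cause. Fasting and Foxo targets changed direction in the difference between stages without members shared with another list (0.0499), which removes members by construction.

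Named genes kept direction and side of the threshold under most alternatives. At 24 hpf 627 of the values without single libraries did, 19 lost and 2 gained a call. At 48 hpf 567 did, 2 lost and 1 gained a call. Library size only ended 3 calls of named genes at 24 hpf and 0 at 48 hpf. RLE size factors ended 1 at 24 hpf. Lists at 24 hpf kept theirs in 281 leave-one-out values, with 4 lost and 11 gained, and at 48 hpf in 209, with 7 lost and 5 gained. Median signs of lists that were not called turned with library size only at 24 hpf for skeletal and heart muscle, erythroid cells, cartilage, epidermis, photoreceptors, heat shock, hypoxia, lysosome and the Igf axis.

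GEO's labels do not say whether the numbers pair the libraries. After group means were taken off, all 14 libraries correlated best with the library of the other genotype with their own number, a hint at pairs from the data and not from the design. Because 5 of 7 pairs, and not all, exceeded a correlation of 0.1, the block stayed an alternative. With it 502 and 869 genes were called higher and lower at 24 hpf, 1322 and 603 at 48 hpf, and hnf4a was called lower at 24 hpf (adjusted p = 0.00863; 0.00863 to 0.344 over its 18 alternatives), as were apobb.1 (adjusted p = 0.0140; 0.00377 to 0.515) and apoa1b (adjusted p = 0.00840; 0.00226 to 0.396). The gene pla2g12b was called lower at 24 hpf (0.0358) and higher at 48 hpf (0.0358). The Hnf4 list at 48 hpf was not called with it (0.0711), whereas the block called mitochondrially encoded genes higher at 24 hpf (0.0285) and, at 48 hpf, the cell cycle list higher (0.0397) and pigment cells lower (0.0416). Small changes were often missed with these libraries, from depth, spread or the number of libraries, which the simulation did not separate: on simulated data 32.8% of 1.5-fold changes were recovered at 24 hpf and 20.9% at 48 hpf, so a gene that was not called can have changed by that much.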

Other observations

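Both lists of this part are outside the 37 above. They and their tests were chosen only after the rise of isg15 was seen, and the members named after their values. Interferon-stimulated genes, which cells switch on against viruses and in sterile inflammation, were higher in mutants at 48 hpf. Of 25 tested, 8 were called higher by edgeR (median log2 fold change 1.22). Beside isg15 and irf1b these were irf7 (1.78 ± 0.35) and irf9 (1.31 ± 0.19), transcription factors of the response, dhx58 (3.56 ± 0.72), a sensor of viral RNA, parp9 (1.68 ± 0.42), ifit14 (4.86 ± 1.01) and ifit15. At 24 hpf isg15 and irf1b (2.13 ± 0.45) were higher, and gbp1, a GTPase of the response, fell by 1.37.

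Genes of antigen processing, which load peptides on class I molecules, rose at 48 hpf in 7 of 15 (median 1.80; 5.24e-05 by limma camera with an estimated correlation). Peptide transporters tap1 (4.03 ± 0.66) and tap2t (1.52 ± 0.31), proteasome activators psme1 (3.10 ± 0.58) and psme2 (2.68 ± 0.49), and b2m (2.00 ± 0.39) and b2ml (0.67 ± 0.17), the light chains of class I molecules, rose. The remaining called gene, tap2a, was listed at 0 in the 48 hpf siblings, so no fold is given. At 24 hpf the median was -0.073 (0.445 with an estimated correlation). The difference between stages was 2.12 in the median, with 5 members called (9.01e-05 with an estimated correlation).

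If an interferon response explains isg15, the other genes of its list should rise at both stages. Without isg15 the camera test with an estimated correlation gave 0.153 at 24 hpf (1 higher and 1 lower of 24 called, median 0.17) and 1.28e-04 at 48 hpf (7 of 24 higher, median 1.18). Without irf1b as well, the values were 0.275 and 2.53e-04. Without isg15 the list rose more at 48 than 24 hpf (8.05e-04 by that test), but isg15 rose at both (7.99 and 8.99). At 24 hpf an interferon response cannot be told apart from another reason for that rise. In raw counts isg15 had 2 to 8 in the 24 hpf sibling libraries and 727 to 1536 in the mutants, so a sequence variant or another gene copy that differs between the groups stays open and was not tested.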
